A study of Mus musculus with 24 samples.

How the data were processed

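The 24 libraries came from mouse embryos in a study of cranial neural crest cells. Per the labels' protocols, cells were cross-linked with paraformaldehyde and promoter capture Hi-C was made with the restriction enzyme HindIII. The protocols name collection by fluorescence-activated sorting for the neural crest of Wnt1::Cre;ROSA-RFP and Ezh2cKO embryos and no other embryos. Whether cells of the deletion embryos were sorted is therefore not given in the sources used here. Each library had its own batch label, so batch was not tested. The E10.5 stage named in the series design was not analysed here.

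The deposited files list called interactions, 1 library per file, each with a promoter-containing HindIII fragment (bait), its other end and a score. Per the submitters' processing notes, coordinates are in GRCm38 (mm10). Per the deposited file names, each score comes from CHiCAGO, which scores a fragment pair against the background expected in its own library, and the lists hold scores of 5 or more. The aligner, the version of the caller and its settings are not given in the sources used here. Read counts were not used here, so read depth was unknown and no count model was fitted. Scores were not compared between libraries, because each is relative to its own library's background. The values analysed were the number and the presence of called interactions.

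Groups followed the sample titles, which number 2 biological replicates in every group except the 42kb deletion, whose titles number 2 libraries without calling them biological. The numbers do not pair samples of different groups. The genotype field of PA2 36kb deletion replicate 2 holds the title of another sample, and its group was taken from its own title. What PTE stands for, which driver made the conditional knockout, and where the deletions lie are not given in the sources used here. The comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

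Baits were the 22203 fragments listed in the first position in any library. They were named with RefSeq genes of GRCm38.p6. The plan was to use transcription start sites, but the table gives no strand, so a bait took the name of each protein-coding gene with either annotated end inside it or, where there was none, within 1 kb. In this way 16237 baits received names, 3233 of them several, and 3872 protein-coding genes had no bait. A name can therefore rest on the far end of a gene. Of the baits, 71.3% held an annotated end of a protein-coding gene, and 19.8% did after the gene ends were shifted by 50 kb, which checks the build.

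For each library, called cis interactions per bait were counted, and log2 of the count plus 0.5 per total called cis interactions was analysed. The 10344 baits with a mean of at least 5 calls were fitted with limma 3.58.1 in R 4.3.3 (12 group means, empirical Bayes with trend), which shares the spread over all groups, and contrasts were tested two-sided. Adjusted p-values are Benjamini-Hochberg over the baits of a contrast, with a threshold of 0.05, and the percent recovered came from simulated changes in 200 baits. Because the values are relative to a library's total, a change common to all baits would not show. For the stage, Ezh2cKO and 36kb contrasts the groups compared were averages over tissues. The F tests asked for any difference between tissues and for any difference of the Ezh2cKO effect between tissues.

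The named-gene rule took, for stage, Ezh2cKO and each deletion, the 10 largest rises and the 10 largest falls past the threshold among named baits, and 5 each way for single tissues. It added up to 10 baits past the threshold from the Hox, frontonasal, maxillary, mandibular, second arch and early neural crest lists, and always a few genes, among them Hoxa2, Hoxa3 and Ezh2. Some genes that the rule takes are not reported here. For lost and gained interactions it took the 10 with the highest median score and a named bait, and up to 15 joining genes of 2 lists. Examples among the genes so chosen were preferred where they kept their call without any 1 library.

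The gene lists were Hox cluster genes, developmental patterning genes outside Hox, frontonasal, maxillary, mandibular and second arch genes, early neural crest and neural plate genes, and skeletal and connective tissue genes. Lists for other cell types or as controls held epithelial, endothelial, muscle, neuronal and glial, blood, housekeeping and Polycomb subunit genes. They were written from general knowledge and share members: 14 of the 14 frontonasal and 52 of the 189 patterning genes are in another list. Each list was tested with camera of limma at a preset correlation of 0.01, adjusted over the 15 lists of a contrast, and again with the correlation estimated from the data.

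Contacts between developmental promoters were counted among called pairs of 2 baits, in trans or in cis at 100 kb or more, as the percent joining 2 genes of the Hox or patterning lists. Means were compared by exact two-sided permutation of libraries, within tissue for Ezh2cKO and the deletions and over all WT libraries compared for stage. An interaction was lost when at least 7 of 8 WT and at most 1 of 8 Ezh2cKO libraries called it, and gained in the opposite case. Replicate concordance was tested by permuting replicate partners.

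The interval of each deletion was planned as the longest run of fragments within 3 Mb of Hoxa2 that WT Md and PA2 libraries called and no deletion library did. After the data were seen, a second rule took fragments with a mean of at least 3 WT calls and at most 10% of them in deletion libraries, joined across gaps of up to 20 kb, and kept the run with most WT calls. Hoxa2 interactions outside the longest runs of both deletions were counted by side and distance. After the data were seen, calls at 0.5 Mb or more outside the depleted run were fitted with limma over the 13799 baits with a mean of at least 1 such call.

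Alternatives were a score of at least 10, lists of equal length, scaling by the median of ratios, a pseudocount of 2, a mean of at least 1 call, cis distances up to 2 Mb, only the compared groups in the fit, a replicate block, and leaving out each library in turn. For promoter pairs they were other distances, denominators and lists, and for lost and gained interactions other thresholds and a 10 kb tolerance. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.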

Results

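Promoter capture Hi-C was measured in mouse embryos to study cranial neural crest cells, the migratory embryonic cells that build much of the face. In this assay, chromatin is cross-linked, digested and ligated so that DNA touching in the nucleus is joined, and junctions that hold a gene promoter are pulled out with probes. The 24 libraries fell into 12 groups of 2 replicates, which the titles call biological except in the 42kb deletion group. They comprised E8.5 wild-type (WT) progenitors, 4 facial tissues at E11.5 in WT and Ezh2cKO embryos, and 3 groups carrying a deletion called Hoxa2PTE. The tissues were FNP, Mx, Md and PA2, abbreviations embryologists commonly use for the frontonasal, maxillary and mandibular processes and the second pharyngeal arch, which the labels do not spell out. Ezh2 encodes the enzyme of Polycomb repressive complex 2 that methylates lysine 27 of histone H3, and Ezh2cKO is its conditional knockout. The 36kb deletion was profiled in Md and PA2 and the 42kb deletion in PA2. Whether the deletion libraries hold sorted neural crest cells is not given in the sources used here. Each library listed between 142284 and 190343 called interactions, each with a score of at least 5, and read depth was unknown. P-values of the limma fits below measure the spread between replicate libraries. Exact tests permute libraries, and for stage they pool the 4 E11.5 tissues, so the spread between tissues enters. List tests compare promoters of a list with other promoters, and Fisher's tests take interactions as units. Whether the 2 libraries of the 42kb deletion are biological replicates is not given in the sources used here.

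Replicates shared more interactions than libraries of different groups did. The median share of called cis interactions held in common (Jaccard index) was 0.315 over the 12 replicate pairs and 0.266 over the 264 pairs from different groups, a difference of 0.0491 (two-sided permutation p = 1e-05, the smallest these permutations can give). Of the 24 libraries, 14 were closest to their own replicate. E8.5 progenitors and E11.5 WT libraries shared fewer, with a median of 0.223 over 16 pairs, against 0.302 over 24 pairs of different WT tissues at E11.5. The E8.5 libraries held 159035 ± 5817 called interactions (SD, n = 2) and the E11.5 WT libraries 171491 ± 2497 (n = 8; two-sided exact p = 0.0444, adjusted p = 0.107 over 20 library tests). Libraries of the 36kb deletion held 150213 ± 5582 (n = 4) against 171503 ± 1408 in their WT controls (n = 4; exact p = 0.0556, adjusted p = 0.107), and 0.0556 was the smallest p that design allows.

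The first comparison asked how promoter contacts differed between E8.5 progenitors and E11.5 facial neural crest (WT libraries, n = 8 at E11.5 and n = 2 at E8.5). The Six2 promoter, of a homeobox factor kept in mesenchymal progenitors, rose from 6.50 ± 0.71 to 30.4 ± 7.46 calls (log2 change 2.01, SE 0.16, adjusted p = 1e-08). Alx4, a homeobox factor of facial mesenchyme, rose from 3.50 ± 3.54 to 27.0 ± 12.1 (2.92, SE 0.38, adjusted p = 5.49e-06), and Ets1, a factor expressed in migrating crest, from 1.50 ± 0.71 to 17.4 ± 5.83 (3.05, SE 0.30, adjusted p = 1.66e-07). Smad7, which encodes an inhibitor of TGF-beta and BMP signalling, had the largest rise among promoters not listed at 0 in both E8.5 libraries. It went from 0.50 ± 0.71 to 57.5 ± 9.32 calls (5.95, SE 0.25, adjusted p = 4.17e-13). At so low an E8.5 count, the size of this change depends on the added 0.5. Among promoters that fell was Cxcr4, the receptor for the chemokine Cxcl12, from 32.0 ± 0 to 4.75 ± 1.91 calls (−2.86, SE 0.49, adjusted p = 0.000146).

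Of 10344 promoter fragments tested between the stages, 1987 called more interactions at E11.5 and 1025 fewer, and the median log2 change over all of them was 0.05. Hmgb1, which encodes an abundant chromatin protein, and Flrt2, a cell-surface adhesion protein, followed Smad7 among promoters with calls at E8.5, with log2 changes of 4.58 (SE 0.47, adjusted p = 2.38e-07) and 4.52 (SE 0.28, adjusted p = 2.17e-10). Medag, Mettl17, Lrp1b, Cntnap2 and Celf6 also rose and were listed at 0 in both E8.5 libraries. The D-lactate dehydrogenase gene Ldhd fell by 2.97 (SE 0.64, adjusted p = 0.00146) and the mitochondrial glutamate carrier gene Slc25a18 by 2.84 (SE 0.41, adjusted p = 2.21e-05). The count of 3012 changed fragments rested on 2 E8.5 libraries and became 1693 without E8.5 replicate 1 and 1685 without replicate 2. In this comparison 23% of simulated 2-fold changes were recovered. The simulation changed far fewer fragments than the 3012 called, so it does not give the share of real changes missed.

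Of 12 frontonasal promoters, 8 rose and 2 fell, and adjusted over the list alone also 8 and 2 (list test adjusted p = 0.0621). Six2 and Alx4 were among those that rose. In the mandibular list 4 of 14 rose and none fell, 4 adjusted over the list alone (list adjusted p = 0.249), and Alx4 is also in this list. Of 37 Hox promoters, 7 fell and none rose (7 adjusted over the list alone; median −0.32, list adjusted p = 0.0214, but adjusted p = 0.127 with an estimated correlation). Hoxb9 changed by −0.97 (SE 0.25, adjusted p = 0.00621; adjusted p = 0.17 without E8.5 replicate 2), and each of the other 6 lost its call without at least 1 E8.5 library, at adjusted p between 0.0845 and 0.329. Hoxa2 and the fragment shared by Hoxa3, Hoxa7 and Hoxa9 did not pass (adjusted p = 0.367 and 0.0742).

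The remaining lists did not pass their list test between the stages. In the patterning list, transcription factors and signals outside the Hox clusters that set up body regions, 41 of 153 promoters rose and 21 fell (43 and 24 adjusted over the list alone; list adjusted p = 0.575). Maxillary promoters had 5 rises and 2 falls of 11 (5 and 3 over the list alone; adjusted p = 0.4), second arch promoters 5 and 3 of 12 (6 and 4; adjusted p = 0.575) and early neural crest promoters 6 and 2 of 19 (6 and 2; adjusted p = 0.4). Skeletal promoters had 4 rises and 1 fall of 17 (4 and 1; adjusted p = 0.249), and Polycomb subunits 1 and 3 of 13 (2 and 3; adjusted p = 0.513). Among markers of other cell types, endothelial promoters had 2 rises and 2 falls of 6 (2 and 2; adjusted p = 0.853), blood 0 and 2 of 11 (0 and 2; adjusted p = 0.178), neuronal and glial 0 and 1 of 4 (0 and 1; adjusted p = 0.812), epithelial 1 and 0 of 6 (0 and 0; adjusted p = 0.801) and muscle 0 and 0 of 7 (0 and 0; adjusted p = 0.307). Housekeeping promoters had 5 rises and 5 falls of 38 (5 and 5; adjusted p = 0.35). The median and the list test differed in sign for the epithelial and the neuronal and glial lists.

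**Figure D1:**
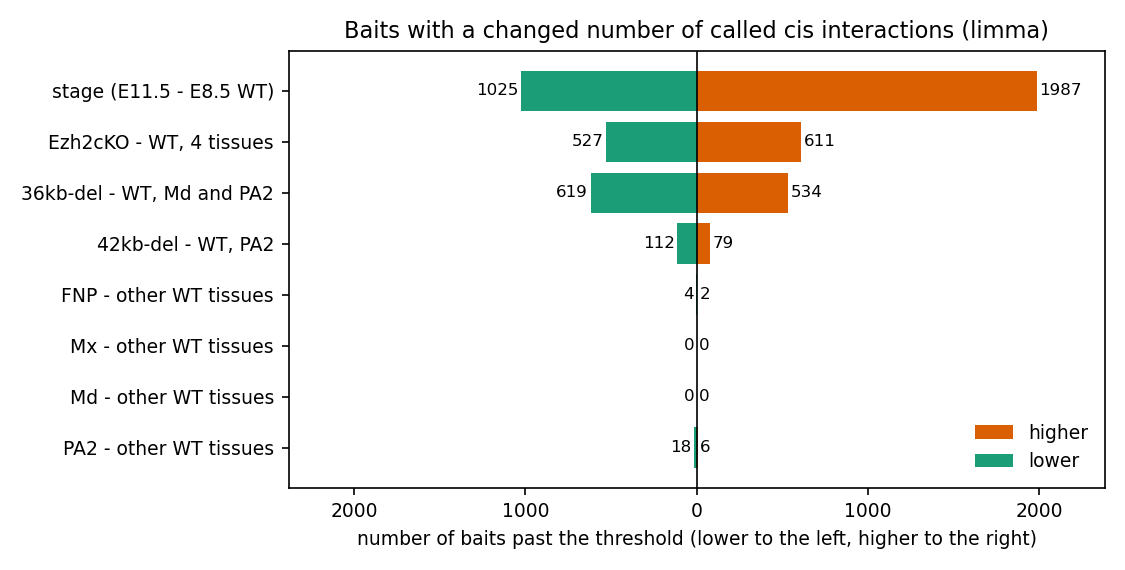
Horizontal bars give the number of promoter fragments with more (right) or fewer (left) called cis interactions at an adjusted p under 0.05, out of 10344 tested, for stage, Ezh2cKO, both deletions and each E11.5 WT tissue against the other 3. The stage comparison has 1987 higher and 1025 lower fragments, Ezh2cKO 611 and 527, the 36kb deletion 534 and 619, and the 42kb deletion 79 and 112.

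The Ezh2cKO comparison asked which promoter contacts depend on this Polycomb enzyme (8 Ezh2cKO against 8 WT libraries over 4 tissues at E11.5). Promoters of developmental transcription factors lost called interactions in Ezh2cKO. Mnx1, the motor neuron homeobox gene, fell from 61.4 ± 7.21 to 5.25 ± 1.83 calls (−3.51, SE 0.12, adjusted p = 7.54e-15). Pax6, a regulator of eye and forebrain, fell from 27.0 ± 4.60 to 1.38 ± 1.06 (−4.17, SE 0.33, adjusted p = 1.14e-08), Wt1, a regulator of kidney and gonad, from 21.5 ± 2.33 to 0.75 ± 1.04 (−4.53, SE 0.33, adjusted p = 3.56e-09) and Zic1, a neural plate and crest regulator, from 27.8 ± 3.77 to 5.12 ± 1.55 (−2.39, SE 0.18, adjusted p = 3.56e-09). Hoxb9, a posterior Hox gene, rose from 17.0 ± 6.21 to 46.4 ± 7.17 calls (1.47, SE 0.16, adjusted p = 1.47e-06).

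Of the 10344 promoter fragments, 611 rose and 527 fell in Ezh2cKO. The fragment at Ezh2 itself averaged fewer than 5 calls and was not tested, so contacts do not check the genotype labels here. Besides Wt1 and Pax6, the largest falls included those of Nkx2-4, Tlx1, Nkx2-3 and Vgll2, all encoding transcriptional regulators, and of Hoxb13, with log2 changes from −4.13 to −3.57. The largest rises included Sema5b, an axon guidance gene (2.16, SE 0.34, adjusted p = 0.000203), and Gsdmd, the pore-forming protein of pyroptosis (1.88, SE 0.28, adjusted p = 0.000106). The gene of the GLP-1 receptor, Glp1r, had 22.9 ± 4.05 calls in Ezh2cKO and was listed at 0 in all 8 E11.5 WT libraries. It had 4.5 ± 2.12 at E8.5, 10.2 ± 3.77 with the 36kb deletion and a mean of 1 with the 42kb deletion. Whether the mouse lines differ in genetic background is not given in the sources used here. Within single tissues, 86 fragments changed in FNP, 129 in Mx, 188 in Md and 167 in PA2. A test of whether the effect differed between tissues passed for 1 fragment, that of Pax3.

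In Ezh2cKO, 70 of 153 patterning promoters fell and 6 rose (82 and 10 adjusted over the list alone; median −0.40, list adjusted p = 9.38e-28, and adjusted p = 2.05e-05 with an estimated correlation). Early neural crest promoters included 7 falls and no rise among 19 (7 over the list alone; list adjusted p = 1.41e-05), among them Foxd3, a factor that maintains crest progenitors (from 11.2 ± 3.45 to 2.88 ± 1.36 calls, adjusted p = 0.000264), and Pax3, a regulator of dorsal neural tube and crest (−1.48, SE 0.11, adjusted p = 7.46e-09). Frontonasal promoters had 5 falls and 1 rise among 12 (5 and 1 over the list alone; list adjusted p = 1.18e-05), led by the 2 fragments of Zic1. The calls of both lists held with an estimated correlation (adjusted p = 0.003 and 0.0021). Of 4 neuronal and glial promoters, 2 fell (2 over the list alone; list adjusted p = 0.000138, and adjusted p = 0.00865 with an estimated correlation), among them Isl1, a neuronal regulator that also belongs to the patterning list and was named after its values were seen.

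The Hox clusters changed in both directions in Ezh2cKO. Of 37 Hox promoters, 10 fell and 7 rose (14 and 8 adjusted over the list alone; median −0.16, list adjusted p = 0.0114, but adjusted p = 0.0812 with an estimated correlation). Falls included Hoxb13 (−3.84, SE 0.33, adjusted p = 3.72e-08), Hoxd1 (−2.37, SE 0.34, adjusted p = 6.25e-05) and Hoxa2, the selector gene of the second arch, from 35.4 ± 17.8 to 15.2 ± 6.45 calls (−1.19, SE 0.17, adjusted p = 6.6e-05). Rises included Hoxb9, Hoxb6 (1.38, SE 0.15, adjusted p = 1.86e-06) and Hoxa13 (0.71, SE 0.12, adjusted p = 0.000556). The fragment of Hoxa3, Hoxa7 and Hoxa9 did not pass (0.03, adjusted p = 0.881). Mandibular promoters had 2 falls and 1 rise among 14 (3 and 1 over the list alone; list adjusted p = 0.0458, but adjusted p = 0.121 with an estimated correlation), with Nkx2-3 and Hand2 lower and Dlx3 higher.

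No other list passed its test in Ezh2cKO. Falls and rises were 1 and 0 of 11 for maxillary (1 and 0 over the list alone; adjusted p = 0.0833), 2 and 2 of 12 for second arch (2 and 2; adjusted p = 0.674) and 0 and 2 of 17 for skeletal promoters (0 and 2; adjusted p = 0.662). They were 1 and 0 of 6 for endothelial (1 and 0; adjusted p = 0.629), 1 and 0 of 7 for muscle (1 and 0; adjusted p = 0.662), 1 and 0 of 11 for blood (1 and 0; adjusted p = 0.496), and 0 and 0 of 6 for epithelial promoters (0 and 0; adjusted p = 0.913). Housekeeping promoters had 2 falls and 5 rises of 38 (2 and 5; adjusted p = 0.496), and Polycomb subunits 0 and 2 of 13 (1 and 2; adjusted p = 0.144). For the second arch and blood lists the median was above 0 while mean and test pointed down.

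Contacts that joined promoters of developmental genes to each other were nearly absent in Ezh2cKO. Among called promoter-promoter pairs at 100 kb or more or on different chromosomes, the share joining 2 Hox or patterning genes was 0.603 ± 0.048% in WT (n = 8) and 0.020 ± 0.005% in Ezh2cKO (n = 8), or 125.9 against 4.0 pairs per library (two-sided exact p = 0.00154, the smallest that permutation within tissues allows; adjusted p = 0.00617 over 12 tests). Pairs between Hox promoters made up 0.18 ± 0.055% in WT and were listed at 0 in all 8 Ezh2cKO libraries (exact p = 0.00154). Of 396 distinct developmental pairs, 187 joined different chromosomes, 393 were called in more WT than Ezh2cKO libraries, and 24 were called in all 8 WT and no Ezh2cKO library. Mnx1 had 6.25 ± 1.04 developmental partners in WT and 0.38 ± 0.52 in Ezh2cKO, and Hoxb13 and Hoxb4 had 7.5 ± 2.45 and 7.25 ± 1.67 in WT and none in Ezh2cKO. Wnt1 had the most, 11.75 ± 0.89 in WT and 0.38 ± 0.52 in Ezh2cKO, and was itself a partner of Hoxb13 and Hoxb4. The pairing of Wnt1 with Hoxb promoters is weighed further below. Pairs between housekeeping promoters, at 0.4 per WT and 0.2 per Ezh2cKO library, were too few to show a loss. Among all calls, pairs of 2 promoters made up 14.3 ± 0.189% of calls in WT and 13.2 ± 0.522% in Ezh2cKO. Pairs between chromosomes made up 3.16 ± 0.163% and 3.84 ± 0.356% (n = 8 each; two-sided exact p = 0.00154 and adjusted p = 0.0154 for both measures). The share was lower at E11.5 than at E8.5 (0.711 ± 0.003%, n = 2; exact p = 0.0444), a difference that did not hold after adjustment (adjusted p = 0.0952).

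**Figure D2:**
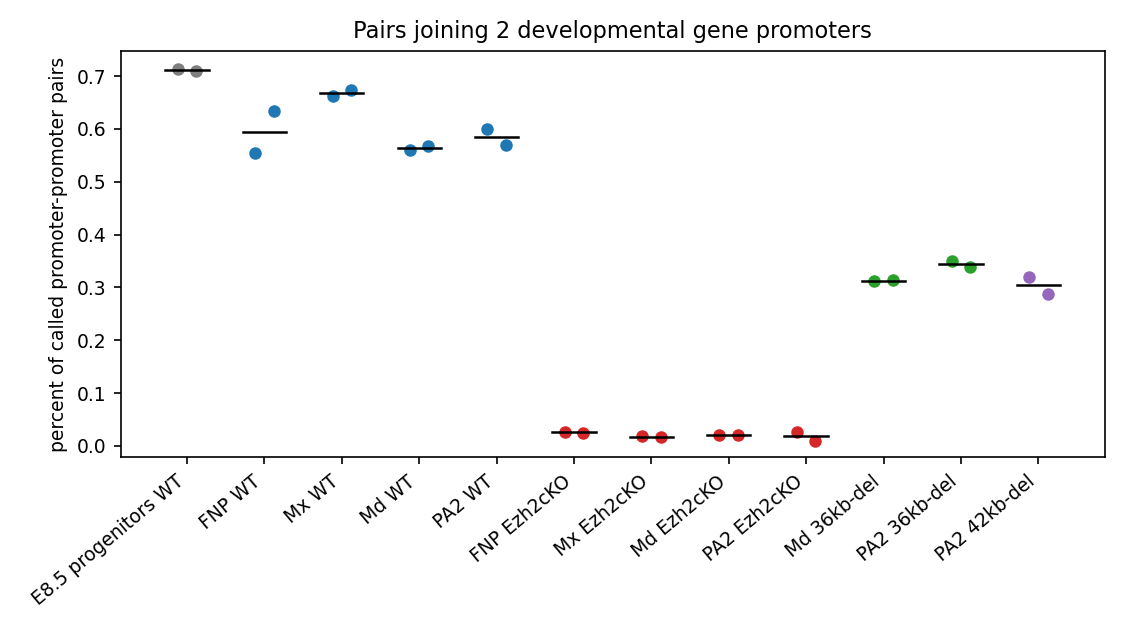
Each point is a library, placed by its group on the horizontal axis, and the vertical axis is the percent of called promoter-promoter pairs that join 2 developmental gene promoters; black lines are group means. The 8 Ezh2cKO libraries average 0.020%, the 8 E11.5 WT libraries 0.603%, the 2 E8.5 libraries 0.711%, and the 36kb deletion libraries 0.328%.

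Single interactions told the same genotypes apart. Called in at least 7 of 8 WT and at most 1 of 8 Ezh2cKO libraries were 1589 interactions (lost), and 1150 showed the opposite (gained). A Hox or patterning promoter took part in 676 (42.5%) of the lost interactions, against 3062 of the other 69245 interactions called in at least 7 libraries of either genotype (odds ratio 16.0). It took part in 102 (8.87%) of those gained, against 3636 of the other 69684 (odds ratio 1.77, two-sided Fisher's exact p = 4.96e-07). Both ends were developmental promoters in 51 lost interactions (odds ratio 67.5, Fisher's exact p = 1.05e-61) and in none gained. Interactions of 1 promoter are not independent, so these p-values overstate the evidence. In each direction, the 10 interactions with a named bait and the highest median score all joined different chromosomes. Among lost pairs joining genes of the lists, En2, a midbrain gene, was joined to Mnx1 over 1307 kb. Others joined Tbx18 to Zic1 over 3627 kb and the forkhead gene Foxa2 to Nkx2-4 over 962.2 kb. Lost pairs between Hoxb promoters on chromosome 11 and Wnt1 on chromosome 15, each called in at least 7 WT libraries, included those of Hoxb8, Hoxb4 and Hoxb2. Wnt1 contacts with chromosome 11 near 6.3 Mb averaged 294.2 ± 14.1 per WT and 318.4 ± 21.8 per Ezh2cKO library and were listed at 0 in all 6 deletion libraries.

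Between E11.5 WT tissues few promoters differed. A test over the 4 tissues passed for 28 of 10344 fragments, a count of 11 without FNP replicate 1, 15 and 14 without Mx replicates 1 and 2, 17 without Md replicate 1, and 7 and 13 without PA2 replicates 1 and 2. Against the other 3 tissues, PA2 had 6 fragments higher and 18 lower, and FNP 2 higher and 4 lower. For Mx and Md, limma called 0 fragments, with 712 and 669 at an unadjusted p under 0.05. In PA2, Hoxb2, a Hox gene of hindbrain and second arch, called 6.50 ± 2.12 interactions against 27.3 ± 6.31 in the other tissues (−1.99, SE 0.27, adjusted p = 0.00134; adjusted p = 0.0721 without PA2 replicate 1).

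Hox promoters as a list were higher in PA2, with 2 rises and 1 fall of 37 (4 and 1 adjusted over the list alone; list adjusted p = 0.0139, but adjusted p = 0.208 with an estimated correlation). The maxillary list had 1 rise and no fall of 11 in PA2 (2 and 0 over the list alone; list adjusted p = 0.0453, but adjusted p = 0.531 with an estimated correlation). Second arch promoters had 1 rise and 1 fall of 12 in PA2 (1 and 1 over the list alone; adjusted p = 0.641). Frontonasal promoters in FNP did not pass as a list (adjusted p = 0.166), with none of 12 changed, and no list passed in Mx or Md.

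The Hoxa2 promoter (chromosome 6, 52162863 to 52166906, mm10) reached distant DNA in PA2. It called 64.0 ± 0 cis interactions in PA2 WT (n = 2) and 25.8 ± 2.56 in the other E11.5 WT tissues (n = 6; 1.31, SE 0.28, adjusted p = 0.0494); leaving out any 1 of the 8 libraries moved this adjusted p to between 0.0748 and 0.312. With the fragments missing in the deletion libraries left out, both PA2 WT libraries called 51 interactions 1 to 2 Mb away toward lower coordinates. The other E11.5 WT libraries called at most 1 there and the E8.5 libraries 0. Interactions under 0.5 Mb ran the other way, with 0 in both PA2 WT libraries and at least 11 in each of the other E11.5 WT libraries. Over calls at 0.5 Mb or more, Hoxa2 was the only 1 of 13799 promoter fragments higher in PA2 (limma, 3.63, SE 0.56, adjusted p = 0.00288), and 6 were lower. This test was chosen after seeing the data, and the Hoxa2 call was lost when PA2 replicate 1 or 2 was left out.

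Distant Hoxa2 interactions in mutant PA2 were compared with those of the same 2 PA2 WT libraries each time. All 6 deletion libraries lacked the chromosome 11 contacts of Wnt1 found in every WT and Ezh2cKO library. Cells collected without the sort, or another mouse line, therefore cannot be told apart from either deletion here. PA2 libraries called 53.5 ± 0.71 at 0.5 Mb or more in WT, 4.0 ± 2.83 in Ezh2cKO, 9.0 ± 1.41 with the 36kb deletion and 3.0 ± 0 with the 42kb deletion (n = 2 each), where the other WT groups had means of 3 to 8. Calls under 0.5 Mb in PA2 ran the other way, at 0 in WT and 11.0 ± 2.83, 6.5 ± 2.12 and 7.5 ± 0.71 in the 3 mutants. In the other tissues such calls were lower in Ezh2cKO than in WT. Means were 4.5 against 12.5 in FNP, 3.5 against 16.0 in Mx and 3.5 against 12.0 in Md. With the 36kb deletion in Md the mean was higher, at 27.0. The share of all cis calls over 1 Mb averaged lower in each mutant over its tissues, without passing adjustment: 25.4 ± 1.17% with the 36kb deletion against 30.7 ± 1.38% (n = 4 each; exact p = 0.0556, adjusted p = 0.107), 23.8 ± 0.693% with the 42kb deletion against 30.4 ± 0.544% (n = 2 each; exact p = 0.333) and 27.6 ± 2.74% in Ezh2cKO against 30.4 ± 1.10% (n = 8 each; exact p = 0.017, adjusted p = 0.107). For Hoxa2 at 0.5 Mb or more, the log2 change in Ezh2cKO PA2 was −3.80 (SE 0.68, adjusted p = 0.000868; adjusted p = 0.072 without Ezh2cKO replicate 1), and that of the 42kb deletion −3.83 (SE 0.68, adjusted p = 0.00234; adjusted p = 0.0654 without PA2 WT replicate 1). The 36kb deletion did not pass in PA2 (−2.32, SE 0.68, adjusted p = 0.124). It did with calls to the depleted fragments included (−2.02, adjusted p = 0.00514, the only such alternative). Those fragments were chosen for lacking calls with the deletion, so part of that fall was built in and it adds no evidence. Neither the Ezh2cKO effect in PA2 against that in the other tissues (adjusted p = 0.734) nor the 36kb effect in PA2 against Md (adjusted p = 0.966) passed a test of the difference. By the test fixed in advance, counts of Hoxa2 interactions outside the intervals without calls of both deletions were 22.2 ± 8.42 with the 36kb deletion and 29.2 ± 9.57 in WT (n = 4 each, exact p = 0.333). This mean joined opposite differences, 15.5 ± 3.54 against 37.5 ± 0.71 in PA2 and 29.0 ± 4.24 against 21.0 ± 1.41 in Md (n = 2 each; exact p = 0.333 for both, the smallest possible). The counts were 10.5 ± 0.71 with the 42kb deletion against 37.5 ± 0.71 (n = 2 each, exact p = 0.333, the smallest possible). The intervals left out ended at 51180766, and the depleted DNA at 51213428. WT calls to the rest of the depleted DNA stayed in these counts, so part of a lower count with a deletion was built in.

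**Figure D3:**
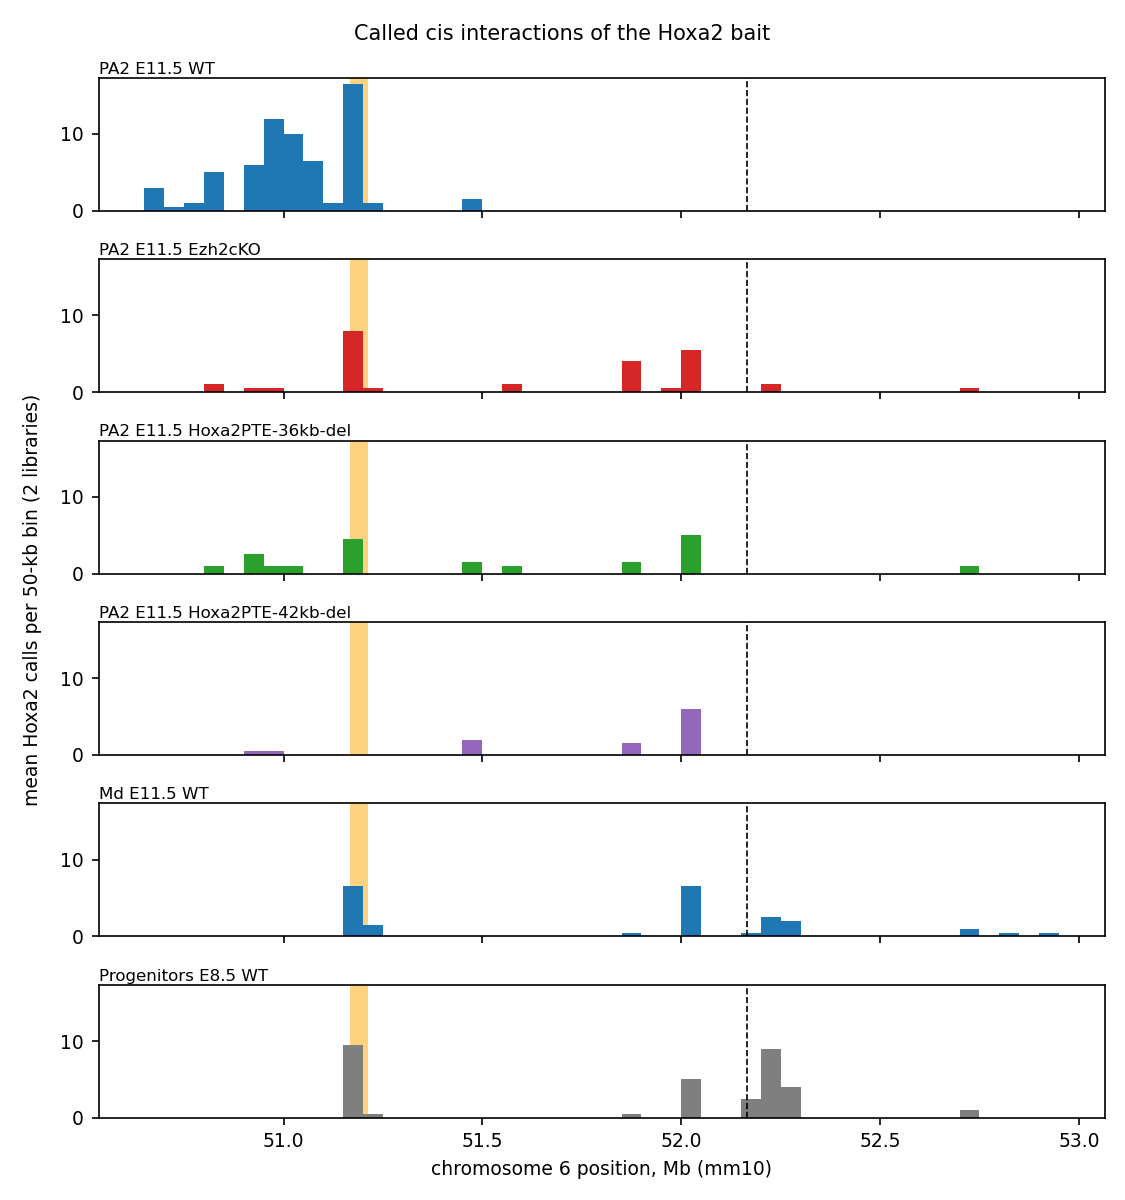
Bars give the mean number of called Hoxa2 interactions per 50 kb bin over 2 libraries, against the position on chromosome 6 in Mb (mm10), for PA2 WT, PA2 Ezh2cKO, PA2 with either deletion, Md WT and E8.5 WT; the dashed line marks the Hoxa2 promoter and the shaded span the DNA depleted in deletion libraries. PA2 WT has its highest bin, 16.5 calls, in the bin that starts at 51150 kb, at the lower edge of the shaded span.

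The deletion libraries lacked calls in part of the DNA that Hoxa promoters contact. The run of depleted fragments with most WT calls, a rule chosen after seeing the data, spanned chromosome 6 from 51173834 to 51213428 (39.6 kb, 9 fragments) for the 36kb deletion and from 51167210 to 51213428 (46.2 kb, 12 fragments) for the 42kb deletion. WT libraries held 99.8 ± 3.40 calls in the first and 36kb deletion libraries 0.25 ± 0.50 (n = 4 each). The rule itself selects this contrast, which does not check the genotype labels. The interval lay 0.97 Mb from Hoxa2, between the protein-coding genes Npvf and Gm38821, and overlapped the long non-coding gene Gm32403 (51200919 to 51207351). The rule fixed in advance, the longest run without calls, gave other spans, of 152.4 kb (51014853 to 51167209), which does not overlap the depleted run, and 96.5 kb (51084309 to 51180766).

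Hoxa promoters contacted this interval in every WT tissue. The 9 named Hoxa fragments made 58.4 ± 3.20 calls to it in E11.5 WT libraries (n = 8), 38.0 ± 2.62 in Ezh2cKO (n = 8) and 47.0 ± 0 at E8.5 (n = 2). The interval was chosen partly for its many calls in Md and PA2 WT, so tests were limited, after the data were seen, to FNP and Mx. There, WT libraries made 55.8 ± 1.71 calls and Ezh2cKO libraries 36.5 ± 2.52 (n = 4 each, two-sided exact p = 0.0556, unadjusted and the smallest possible). WT against E8.5 gave exact p = 0.133, likewise unadjusted and the smallest possible, so this test could not have passed. The calls were listed at 0 in the 36kb deletion libraries, by which the interval was chosen, and averaged 0.50 ± 0.71 with the 42kb deletion (n = 2), whose libraries did not enter that choice. The fragment of Hoxa3, Hoxa7 and Hoxa9 called it most often over the 8 WT libraries, 71 times, against 47 for Hoxa2.

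**Figure D4:**
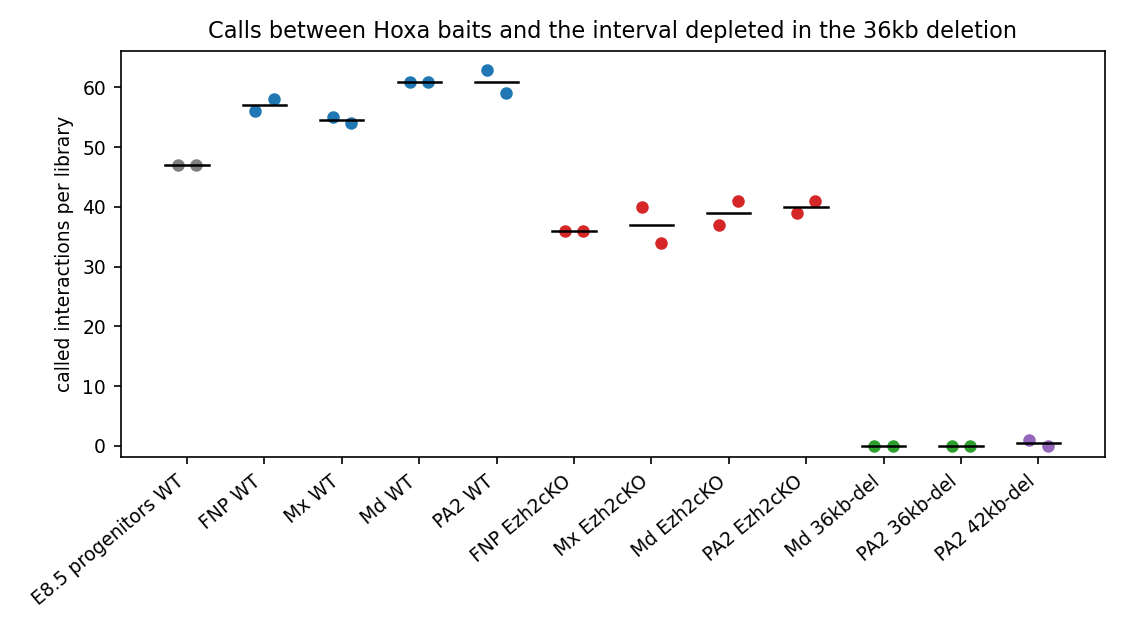
Each point is a library, by group on the horizontal axis, and the vertical axis is the number of called interactions between the 9 Hoxa promoter fragments and the interval depleted in the 36kb deletion; black lines are group means. E11.5 WT libraries average 58.4 calls, Ezh2cKO libraries 38.0, E8.5 libraries 47.0, and 36kb deletion libraries 0.

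Beyond the Hoxa locus, the 36kb deletion libraries differed from WT at promoters across the genome (Md and PA2, n = 4 each). Among the 10 largest rises were 5 olfactory receptor promoters, such as Olfr1002, going from 1.00 ± 0.82 to 28.2 ± 6.24 (4.63, SE 0.52, adjusted p = 3.01e-05) and Olfr1009 from 7.5 ± 2.52 to 40.2 ± 12.5 (2.53, SE 0.29, adjusted p = 3.01e-05). Sprr2b, a cornified envelope gene of the epidermis, rose from 1.25 ± 0.96 to 18.8 ± 3.20 (3.88, SE 0.50, adjusted p = 9.45e-05). The fragment of the bromodomain gene Brd2 and the antigen-loading gene H2-DMa fell from 30.0 ± 2.00 to 1.75 ± 2.06 (−4.25, SE 0.24, adjusted p = 6.16e-10), and the keratin gene Krt16 from 20.5 ± 1.29 to 3.25 ± 1.50 (−2.39, SE 0.28, adjusted p = 3.22e-05). Dlx3, a homeobox gene of the mandibular arch, fell from 26.2 ± 7.41 to 11.8 ± 1.26 (−0.91, SE 0.20, adjusted p = 0.00598).

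In total 534 fragments rose and 619 fell with the 36kb deletion. The count of 1153 was 637 and 720 without Md WT replicates 1 and 2, 622 and 656 without PA2 WT replicates 1 and 2, 642 without Md deletion replicate 1 and 594 without PA2 deletion replicate 1. It was 712 with only the compared groups fitted. Hoxa2 (−0.52, adjusted p = 0.162) and the fragment of Hoxa3, Hoxa7 and Hoxa9 (adjusted p = 0.454) did not pass. Hoxa2 did with scores of at least 10 (−0.83, adjusted p = 0.02, and 0.02 to 0.187 over 8 alternatives). These counts include calls to the depleted DNA, so part of the Hoxa2 fall was built in. They also average Md and PA2, where Hoxa2 calls outside the intervals differed in opposite directions. The share of developmental promoter pairs was 0.328 ± 0.019% against 0.575 ± 0.017% (exact p = 0.0556, the smallest possible), and these libraries lacked the chromosome 11 contacts of Wnt1 found in every WT and Ezh2cKO library.

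No list passed its test with the 36kb deletion (adjusted p between 0.836 and 0.909). Rises and falls were 6 and 9 of 153 patterning promoters (2 and 2 adjusted over the list alone), 1 and 3 of 37 Hox (0 and 2), 0 and 2 of 14 mandibular (1 and 2), 0 and 2 of 11 maxillary (0 and 2) and 0 and 1 of 19 early neural crest promoters (0 and 0). They were 1 and 2 of 17 skeletal (1 and 3), 2 and 4 of 38 housekeeping (3 and 4), 0 and 1 of 13 Polycomb (0 and 1), 0 and 1 of 7 muscle (1 and 2) and 1 and 0 of 4 neuronal and glial promoters (1 and 1). Frontonasal, second arch, epithelial, endothelial and blood lists had no changed promoter under either adjustment. Mean or median and test differed in sign for the frontonasal, maxillary, housekeeping and Polycomb lists.

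With the 42kb deletion in PA2 (n = 2 each), Hoxa2 fell from 64.0 ± 0 to 10.5 ± 0.71 calls (−2.44, SE 0.34, adjusted p = 0.000956), a count that includes calls to the deleted DNA. The fragment of Hoxa3, Hoxa7 and Hoxa9 did not pass (−0.19, adjusted p = 0.701), though it did with scores of at least 10 (−1.26, adjusted p = 0.0444; 0.0444 to 0.752 over 8 alternatives). Mptx1, a mucosal pentraxin gene, fell from 20.0 ± 5.66 to 0.50 ± 0.71 (−4.42, SE 0.39, adjusted p = 2.59e-06) and Mcts1, a translation re-initiation gene, from 20.5 ± 0.71 to 2.00 ± 1.41 (−3.08, SE 0.45, adjusted p = 0.00161). Olfr1002 rose by 4.18 (SE 0.74, adjusted p = 0.00553; adjusted p = 0.0858 without PA2 WT replicate 2). In all, 79 fragments rose and 112 fell, and the count of 191 was 29 and 40 without PA2 WT replicates 1 and 2, 94 and 124 without deletion replicates 1 and 2, and 70 with only the compared groups fitted. These libraries too held no Wnt1 contacts on chromosome 11, and their share of developmental promoter pairs was 0.304 ± 0.023% against 0.585 ± 0.021% in PA2 WT (exact p = 0.333, the smallest possible). Cells collected without the sort, or another mouse line, cannot be told apart from this deletion either.

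No list passed with the 42kb deletion (adjusted p between 0.437 and 0.753). Rises and falls were 1 and 3 of 153 patterning promoters (1 and 3 adjusted over the list alone), 0 and 1 of 37 Hox (0 and 1), 0 and 1 of 12 second arch (0 and 1), 1 and 0 of 19 early neural crest (1 and 0) and 2 and 1 of 38 housekeeping promoters (2 and 1). They were 0 and 1 of 6 endothelial (0 and 1), 1 and 0 of 4 neuronal and glial (1 and 0), 0 and 1 of 13 Polycomb (0 and 1) and 0 and 0 of 11 maxillary promoters (0 and 1). Frontonasal, mandibular, skeletal, epithelial, muscle and blood lists had no changed promoter. Median or mean and test differed in sign for the endothelial, muscle, neuronal and Polycomb lists. Between the 42kb and 36kb deletions in PA2, 15 fragments were higher and 30 lower with the 42kb deletion.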

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

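The tests of chance, of list length and bait density for the 36kb deletion, of its cell collection, of where Wnt1 contacts lie, and of Hoxa2 calls near the promoter were chosen only after the results were seen.

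The Pax3 promoter stood out because its Ezh2cKO effect differed between tissues (limma F test, adjusted p = 0.00251, the only bait of 10344). The log2 change was −2.61 in PA2 (adjusted p = 4.37e-07) and −2.30 in Md (adjusted p = 2.63e-06), and −0.86 in Mx (adjusted p = 0.0728) and −0.14 in FNP (adjusted p = 0.891), each with SE 0.23. No biological or technical explanation was tested for Pax3. With the 36kb deletion, 2 baits differed between PA2 and Md by a test of the difference. The bait of Tssk4, a testis kinase gene, changed by −3.83 in Md and 0.58 in PA2 (limma, adjusted p = 0.00179), and that of Brd2 and H2-DMa by −5.81 in Md and −2.70 in PA2 (limma, adjusted p = 0.0133).

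Among 19 groups and measures searched for a library far from the others, 2 stood out, and chance gives about 1 in 20. FNP WT replicate 2 had 10 calls from Hoxb promoters to the Wnt1 bait where each other E11.5 WT library had 9, and PA2 Ezh2cKO replicate 1 had 1 where each other Ezh2cKO library had 0.

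Chance assignment of libraries to genotypes was weighed for 4 counts and argued against for the Ezh2cKO counts. The number of arrangements limits how small a chance could be shown. These tests do not separate genotype from mouse line or cell collection. The 1138 fragments changed in Ezh2cKO were reached by 1 of 100 arrangements, the real one, with 323 as the highest of the others. With 1 effect fitted over Md and PA2, the 36kb deletion gave 1146, reached by 1 of 34 arrangements, with 65 as the highest other. Those arrangements of the 8 libraries were not all balanced within tissue, as those for Ezh2cKO were. Arrangements balanced within tissue could give no exact p below 0.0556 in this design, so chance is left undecided for this count. None of 100 other arrangements reached the 1589 lost or the 1150 gained interactions, with 956 as the highest.

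The first pattern weighed was the spread of the 36kb deletion's effect over the genome, far beyond the Hoxa locus. Shorter lists as the whole cause are argued against, since 950 fragments changed with lists of equal length, 784 of them among the 1153 and in the same direction. A trend with the density of baits along the chromosome is argued against as the whole cause, since 823 fragments changed in the same direction before and after its removal. Cells collected without the sort, or another mouse line, cannot be told apart from the deletion: every 36kb deletion library had 0 Wnt1 calls near the chromosome 11 site, where the 18 other libraries outside the deletion groups had 151 to 346. An effect of the deletion itself stays open and untested.

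The second pattern was the Wnt1 bait's pairing with Hoxb promoters on chromosome 11, which enters the developmental pairs lost in Ezh2cKO. Of the Wnt1 bait's calls on other chromosomes, 98.1% lay on chromosome 11, against 24.6% of all calls between chromosomes that touch it, so a copy of Wnt1 sequence inserted there, as a Wnt1 transgene would bring, is a candidate explanation of this pairing. As the whole cause of the lower developmental contacts it is argued against, since 90.7% of the Ezh2cKO difference and 76.6% of the 36kb deletion difference were kept without this bait. Calls of the Wnt1 bait over 10 Mb from the site numbered 69.8 ± 7.32 in WT and 19.4 ± 4.50 in Ezh2cKO (n = 8 each; two-sided exact p = 0.00154, adjusted p = 0.00882), while those within 1 Mb were 294.2 and 318.4 (exact p = 0.037, adjusted p = 0.0889). A biological loss of Polycomb-linked contacts in Ezh2cKO stays a hypothesis.

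The third pattern was the set of Hoxa2 contacts 1 to 2 Mb away in PA2 WT. List length is argued against among the E11.5 tissues. The PA2 WT libraries listed 169967 and 171346 interactions and the other E11.5 WT libraries 168670 to 176164. Cutting to equal length could therefore hardly remove the difference and adds little. With it, the lower of the PA2 WT libraries kept 49 such calls and the other WT libraries had none. Stronger capture of the Hoxa2 bait in PA2 is argued against too, since PA2 WT libraries had 0 Hoxa2 calls under 0.5 Mb where the others had at least 11. A shift in the background that the caller assigns to this bait stays open, because reads were not used here, and it could move near and far calls in opposite directions. A difference between tissues in how Hoxa2 is regulated stays open as well.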

How the results depend on the processing

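Removal of the density trend, the fits without the Wnt1 bait, the depleted run and the Hoxa2 counts at 0.5 Mb or more were alternatives chosen after the data were seen. No cause was tested for any change below, and fewer calls or fewer libraries entered where the setting says so. With scores of at least 10, changed fragments numbered 610 for stage, 242 for Ezh2cKO, 214 for the 36kb deletion, 42 for the 42kb deletion and 6 for tissue, lost and gained interactions 648 and 445, and the intervals without calls 224.6 and 642.4 kb. With only the compared groups fitted, the counts were 712 for the 36kb deletion, 70 for the 42kb deletion and 15 for tissue. Tissue gave 18 with a mean of at least 1 call and 45 for cis distances up to 2 Mb. Lost and gained interactions were 697 and 208 at 8 against 0 of 8, 4615 and 5306 at 6 against 2, and 3718 and 1922 with other ends within 10 kb. The depleted run was 39.6 kb and 46.2 kb long. The stage difference in developmental promoter pairs (percentage points) was −0.1226 with scores of at least 10 (exact p = 0.489), −0.08582 with lists of equal length (exact p = 0.0889), −0.1333 at 1 Mb or more (exact p = 0.444), −0.01687 without Hox genes (exact p = 0.8) and reversed to 2.163 in trans only (exact p = 0.356). For Hoxa2 outside the intervals without calls, the 36kb difference of −7.0 became 3.5 over all Hoxa baits (exact p = 0.889), and the stage difference of −5.625 became 1.625 with scores of at least 10 (exact p = 0.889). With an estimated correlation, 5 list calls were lost: Hox (0.127), Ezh2cKO Hox (0.0812), Ezh2cKO mandibular (0.121), PA2 Hox (0.208) and PA2 maxillary (0.531), the first for stage; the other 115 list results kept their side of the threshold, as all 120 did with the median of ratios. Of 3311 values of named genes under alternatives, 2867 kept direction and side, 432 lost their call, 5 gained one and 7 reversed; those reversed were at stage, up to 2 Mb, Hoxd10/Hoxd9 (0.004), Dlx2 (0.623), Dlx1 (0.844) and Zic2 (−0.04), with scores of at least 10 Tfap2b (0.105), for the 36kb deletion Hoxa11 (−0.238), and the Hoxa2 stage count above. Leaving out 1 library gave 1685 to 2872 changed fragments for stage (1693 and 1685 without E8.5 replicates 1 and 2), 820 to 992 for Ezh2cKO, 594 to 1299 for the 36kb deletion, 29 to 124 for the 42kb deletion and 7 to 25 for tissue, each library that moved a count being named with the result. It gave −0.5924 to −0.5725 for the Ezh2cKO difference in developmental pairs (exact p = 0.00309 throughout), −0.1187 to −0.1017 for stage (exact p = 0.0556 to 0.222, none past the threshold) and −8.5 to −5.5 for Hoxa2. A lone library left in a group was assumed to vary like the other groups. With the density trend removed, 2880 fragments changed for stage, 1116 for Ezh2cKO, 985 for the 36kb deletion and 199 for the 42kb deletion. Without the Wnt1 bait the developmental difference was −0.5281 for Ezh2cKO (exact p = 0.00154) and −0.1577 for stage (exact p = 0.0444).

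The numbers of replicates did not pair libraries: over 66 pairs of groups the median correlation of replicate differences was 0.004, and 1 exceeded 0.1. With a replicate block, 2976 fragments changed for stage, 1120 for Ezh2cKO, 1140 for the 36kb deletion, 177 for the 42kb deletion and 26 for tissue, and the Ezh2cKO difference in developmental pairs was −0.5825 (exact p = 0.00781). Read depth was unknown, so a library with fewer reads could hold fewer calls; with lists of equal length the 36kb deletion gave 950 fragments. Of simulated 2-fold changes 60% were recovered for Ezh2cKO, 40% for the 36kb deletion, 23% for stage and 20% for the 42kb deletion. Of simulated 1.5-fold changes, 29%, 9%, 2% and 1% were recovered, in the same order. For stage, Ezh2cKO and the 36kb deletion the simulation changed far fewer baits than were called. The adjustment depends on how many baits change, so the share of real changes missed there was not measured.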

Other observations

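The counts by gene family and chromosome, and the look at single interactions between chromosomes, were chosen only after the results were seen.

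Changed promoters were counted in 3 clustered gene families; most members did not pass, and no test of the families was run. Of 415 olfactory receptor (Olfr) promoters, 62 were higher and 4 lower with the 36kb deletion (median log2 change 0.24), 83 and 3 with the density trend removed, and 55 and 6 with the median of ratios. In Ezh2cKO, 5 of them were higher and 26 lower (median −0.13), and with the 42kb deletion 6 and 11. Of 50 keratin (Krt) promoters, 1 was higher and 12 lower with the 36kb deletion (median −0.41), which became 4 and 6 with the density trend removed, and 7 were higher and none lower in Ezh2cKO. Of 50 vomeronasal receptor (Vmn) promoters, 1 was higher and 6 lower in Ezh2cKO, 2 were higher and 1 lower with the 36kb deletion, and 4 were lower with the 42kb deletion. Chromosome 7 held 132 lower and 30 higher of 1079 promoters in Ezh2cKO, 138 and 37 with the 36kb deletion and 23 and 6 with the 42kb deletion, each against shared or overlapping WT libraries.

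Within the lost and gained interactions, 146 and 169 joined different chromosomes. These made up 9.19% and 14.7%, against 2.35% of the interactions called in at least 7 libraries of either genotype. The Spata3 promoter on chromosome 1 and a fragment on chromosome 8 (71933176 to 71934931) were joined in 8 of 8 E11.5 WT, 0 of 8 Ezh2cKO, 2 of 2 E8.5, 4 of 4 36kb deletion and 2 of 2 42kb deletion libraries. The Adgrf3 promoter on chromosome 5 and a fragment on chromosome 8 (123431484 to 123435124) were joined in 0 E11.5 WT and 8 Ezh2cKO libraries, in both E8.5 libraries and in all 6 deletion libraries. The promoter of Tril and a fragment on chromosome 19 (58059158 to 58062435) were joined in 8 Ezh2cKO, 2 E8.5 and no other libraries. No explanation of these pairs was tested.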
